A study of Mus musculus with 8 samples.

How the data were processed

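Small RNA libraries of 18 to 35 nt were made from 100 µg of total liver RNA, per the labels' protocols, for 4 offspring of low-protein fathers and 4 of control fathers. Groups and numbers of the livers were taken from the sample titles, and the numbers do not recur between groups, so the labels pair no livers. The deposited files hold sequenced reads, 1 line per cluster with its lane, tile, position and 36 nt read, and no unit of expression, trimming or alignment has been applied to them, per the file contents. The submitters' processing notes name the genome build mm9, which was not used here; the aligner is not given in the sources used here.

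The labels describe 1 adapter ligated to the 3′ end. In the deposited reads 4 libraries carried it directly after the insert and 4 carried a cloning linker first, as judged by which adapter's first 9 bases were found in more reads. Each library was trimmed with its own sequence: the first 6 bases had to match exactly and the rest of the read with at most 25% mismatches, since a 6-base match alone occurs inside miR-143-3p and miR-10a-5p in linker libraries. This second condition was added to the planned rule before miRNAs were counted. Inserts of 18 to 30 nt without an uncalled base were kept. They numbered 3651488 to 4897663 per library. Adapters without insert took 10.3% to 15.0% of reads in linker libraries and 0.992% to 1.42% in direct libraries.

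Reads were matched by their first 20 nt, leaving the 3′ end free, to a panel of 168 mature mouse miRNA sequences written from memory before the data were examined. Of these, 166 were found in annotated hairpins of GENCODE M21 (GRCm38), whose coordinates are printed here, and 2 were dropped. The annotation gives hairpins and not mature miRNAs, so all hairpin arms with at least 80 pooled reads were counted as an alternative. miRNAs with the same 20 nt were merged, which left 165, and miRNAs that differ later than that or are copies of one another, such as miR-199a-3p and miR-199b-3p, share their reads. miRNAs with a mean of at least 10 reads per library were tested, 159 in all. The 5′ ends of 7 tRNAs, also written from memory, were counted in reads with or without a recognised adapter. RNA classes were assigned by the same 20 nt in GENCODE transcripts, where 28S rRNA and most tRNAs are not held, so that part of the unmatched reads belongs to them.

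The planned test for reads deposited without a table of values was limma 3.58.1 in R 4.3.3, with voom weights on log2 RPM, library sizes from the median of ratios and Benjamini-Hochberg adjustment, on all 8 livers without covariates. Values per liver are printed as scaled RPM, with the same library sizes. Count-model tools that had been listed as alternatives were planned for a deposited table of values and were not run. The reads counted here per miRNA could have been given to them. Lists of miRNAs were tested with camera (preset correlation 0.01) and fry; 13 lists were fixed before the data were examined, 11 of which had at least 3 measured members. They cover the let-7 family, the miRNAs named by the study, hepatocytes, lipid and glucose metabolism, the miR-17-92 cluster, mesenchymal, haematopoietic, endothelial, epithelial, striated muscle and neural cells, the Dlk1-Dio3 cluster and the X-linked miR-322 and miR-450 cluster. Single shares were compared with two-sided exact permutation tests, whose smallest p for 4 against 4 is 0.0286, or 0.0556 when livers are exchanged within library types. Python 3.11.15 with numpy 2.4.6 counted the reads and matplotlib 3.10.9 drew the figures.

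The miRNAs named in the text follow a rule fixed before the data were examined: the 10 with the highest mean, every guide-strand member of the study's list, those past the adjusted threshold, the 5 with the smallest p in a direction where fewer than 8 passed, and up to 4 markers of each other cell type with a mean of at least 100 reads. The study's list was recalled from its paper and is possibly incomplete. The fits were tested on simulated data after they had first been run on the real reads: 20 sets with the means, library sizes, library types and spread of the real 159 miRNAs, in each of which 40 miRNAs were changed, 20 by 2-fold and 20 by 4-fold. The fit with library type as a term recovered 74.5% and 94.8% of them, with 4.38% of calls false. The planned fit recovered 14.8% and 56.8%, with 0.348% false. The spread was drawn independently for each miRNA, while real miRNAs can vary together, so these shares may overstate recovery. Many miRNAs were changed at once, which makes the adjusted threshold easier to pass than with few changed. Changes under 2-fold were not simulated. The 8 libraries were counted as separate samples, per the labels. Alternatives planned beforehand were other library sizes, filters, matching rules, weights, a term for the title numbers (1 to 4 against 5 to 8) and leaving out each liver; those chosen after seeing the data were library type as a term, each library type alone, all hairpin arms, reads without a recognised adapter, removal of the GC slope, leaving out low-protein 4 and 8, consecutive title numbers as a block, and exchange of livers within library types. Poisson intervals cover counting error only, since PCR copies cannot be told from molecules.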

Results

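Small RNAs were sequenced from the livers of 8 mouse offspring aged 3 weeks. The fathers of 4 of them had been raised on a low-protein diet and the fathers of the other 4 on a control diet, until they were mated at 9 to 12 weeks of age. The mothers had received the control diet. The series asks whether the diet of the father goes with different small RNAs in the liver of the young. Each library held 5722074 to 8833042 reads of 36 nt, of which 2863009 to 3673078 matched a miRNA of the panel used here. Whether the 4 livers of a group came from separate litters is not given in the sources used here, so p-values measure the spread between these livers.

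The 8 libraries were of 2 kinds. In 4 of them (low-protein 1 and 8, control 2 and 7) the insert was followed by a cloning linker, called the linker libraries here. In the other 4 (low-protein 4 and 5, control 3 and 6) it was followed by the adapter of the labels, called the direct libraries. Each kind held 2 livers of each diet. The reads of every linker library came from 100 tiles of the flow cell and those of every direct library from 330, so the adapter coincides with a difference in the sequencing run. The first principal component of the miRNA levels separated the 2 kinds and held 70.7% of the variance, and limma called 100 of 159 miRNAs different between them at a Benjamini-Hochberg adjusted p under 0.05. The hepatocyte-enriched miR-148a-3p, for example, averaged 5923 scaled RPM (reads per 1000000, with the library size of each liver set by the median of ratios) in the linker and 40545 in the direct libraries. Values within each kind are therefore given beside the pooled ones for some miRNAs. For the others the pooled SD includes any difference between the kinds. The fit with library type as a term was chosen after seeing the data.

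The liver miRNA profile was dominated by miR-122, the hepatocyte miRNA that maintains cholesterol and lipid metabolism, in livers of both groups. miR-122-5p (chromosome 18, 65248866 to 65248887, plus strand, GRCm38, in an exon of AC157910.3) stood at 567779 ± 113973 in low-protein and 656850 ± 156390 in control livers (scaled RPM, SD, n = 4). Scaled RPM are not shares of the reads. As a share of panel miRNA reads, miR-122-5p ranged from 48.3% in low-protein 5 to 73.0% in control 2. The next most abundant were miR-21a-5p, let-7a-5p, let-7f-5p, miR-192-5p and miR-148a-3p, followed by let-7c-5p, let-7d-5p, miR-29a-3p and let-7b-5p. None of the 159 miRNAs tested passed an adjusted p under 0.05 between the diets in the limma voom fit, and 2 had an unadjusted p under 0.05. With library type as a term, limma voom also called 0, and 10 had an unadjusted p under 0.05. The limma-trend fit and the fit with sample quality weights each called 0, with 2 at an unadjusted p under 0.05. A limma voom fit with couples of consecutive title numbers as a block called 4, with 17 at an unadjusted p under 0.05. They were miR-210-3p (log2 difference -0.80, limma adjusted p = 0.0248) and the muscle miRNAs miR-1a-3p, miR-133a-3p and miR-206-3p. This fit was chosen after seeing the data, its calls included, and the titles do not pair the livers. Of the 4 ways to couple a low-protein with a control liver within library types, 2 called 4 miRNAs and 2 called 0.

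The miRNAs named by the study are the growth- and fibrosis-associated miR-21, the let-7 family with miR-98, which share a seed and accumulate as tissues mature, miR-199a of mesenchymal cells and the hypoxia-induced miR-210. Of 13 measured members, 9 had a higher and 4 a lower mean log2 level in low-protein livers. Of these members, 0 passed the limma test over all miRNAs or adjusted over the list alone. The trimmed mean of M values gave 10 higher and 3 lower. Total miRNA reads as the scale gave 12 higher and 1 lower, but moved the median log2 difference of all miRNAs from 0.016 to 0.11. The list was recalled from the paper and is possibly incomplete, and the study chose it on these samples, so its count is not independent evidence. miR-21a-5p (chromosome 11, 86584120 to 86584141, minus strand, GRCm38, within a UTR of Vmp1) was at 43118 ± 13907 in low-protein and 32054 ± 9174 in control livers, a log2 difference of 0.41 ± 0.33 (SE), with 0.43 in the linker and 0.38 in the direct libraries. let-7f-5p was at 39158 ± 16101 in low-protein and 28193 ± 8166 in control livers, with log2 differences of 0.16 in the linker and 0.65 in the direct libraries. let-7a-5p was at 39251 ± 21425 in low-protein and 31895 ± 14298 in control livers, and its log2 differences were 0.039 in the linker and 0.39 in the direct libraries. miR-199a-3p, whose sequence is shared with miR-199b-3p, was at 2844 ± 1888 in low-protein and 2250 ± 1448 in control livers. miR-210-3p (chromosome 7, 141221407 to 141221428, minus strand, GRCm38, overlapping no other gene) was at 250.4 ± 99.6 in low-protein and 432 ± 165 in control livers, and its log2 difference was -0.78 in the linker and -0.82 in the direct libraries. Leaving out 1 liver moved most of these log2 differences. That of miR-21a-5p was 0.21 without low-protein 1 and 0.18 without control 7, and that of let-7f-5p was 0.22 without low-protein 4, 0.25 without low-protein 5 and 0.21 without control 7. That of let-7a-5p lay between -0.039 without low-protein 4 and 0.49 without low-protein 1, and that of miR-210-3p was -0.47 without low-protein 1. Over all such fits, with or without library type as a term, miR-21a-5p ranged from 0.14 to 0.62 and let-7f-5p from 0.21 to 0.60. The range of miR-210-3p was -1.15 to -0.47, and miR-21a-5p, let-7f-5p and miR-210-3p kept their sign. With library type as a term the log2 difference of miR-210-3p was -0.79 ± 0.32, at a limma adjusted p of 0.593. The remaining members were let-7g-5p at a log2 difference of 0.27 ± 0.23, let-7c-5p at 0.18 ± 0.44, let-7d-5p at 0.20 ± 0.65, miR-98-5p at 0.21 ± 0.26, miR-199a-5p at 0.14 ± 0.22, let-7b-5p at -0.0073 ± 0.42, let-7e-5p at -0.034 ± 0.44 and let-7i-5p at -0.032 ± 0.26. Without control 2 that of let-7g-5p was 0.13. That of miR-98-5p was 0.043 without control 7, 0.11 without low-protein 4 and 0.36 without control 3, and that of miR-199a-5p 0.063 without low-protein 5, 0.074 without control 2 and 0.092 without control 3. The sign of the other 6 turned with 1 liver left out, from -0.049 without low-protein 5 to 0.68 without low-protein 1 for miR-199a-3p, -0.054 without low-protein 4 to 0.45 without low-protein 1 for let-7c-5p and -0.25 without control 2 to 0.54 without control 3 for let-7d-5p. The ranges were -0.24 without control 2 to 0.27 without low-protein 1 for let-7b-5p, -0.32 without low-protein 4 to 0.17 without low-protein 1 for let-7e-5p and -0.25 without low-protein 8 to 0.044 without control 7 for let-7i-5p. Leaving out 1 liver makes the diets unequal by library type, so differences between the types can enter fits without that term. The log2 difference of linker minus direct libraries was -1.84 for miR-199a-3p, -1.74 for let-7d-5p, -1.31 for let-7a-5p and -1.09 for let-7c-5p. Such shifts cannot be laid to the single liver alone.

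**Figure D1:**
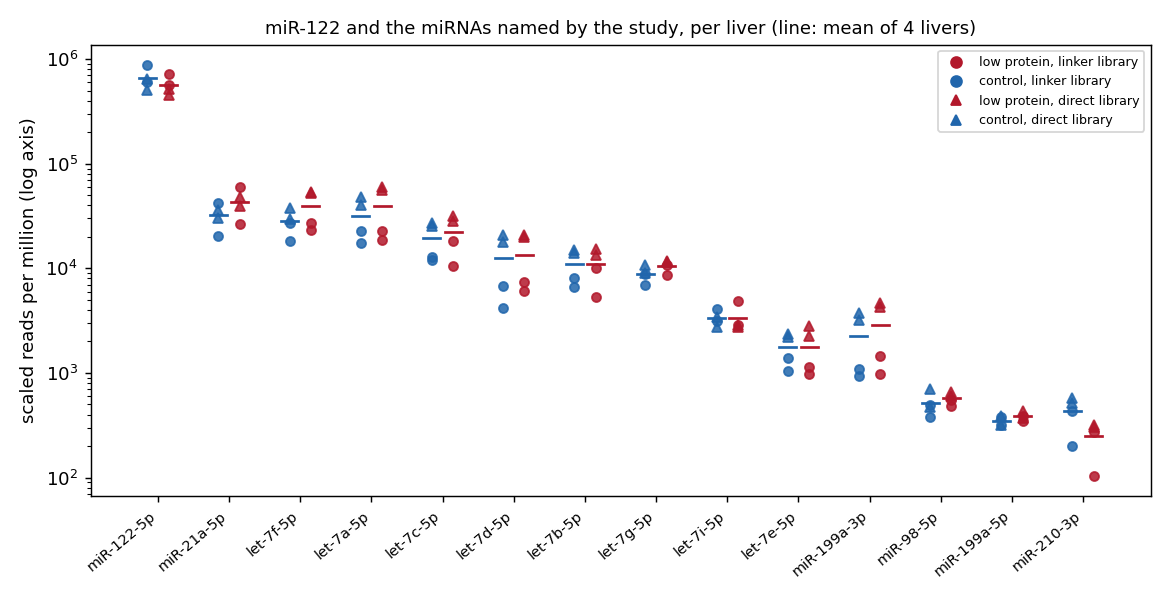
Scaled RPM (log axis) of miR-122-5p and the miRNAs named by the study in each of the 8 livers, with the symbol giving the library type and the line the mean of the 4 livers of a diet. For let-7a-5p, let-7d-5p and miR-199a-3p the livers fall apart by library type more than by diet.

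As a share of miRNA reads, the let-7 family made up 14.7% ± 6.11 in low-protein and 11.4% ± 4.19 in control livers (SD, n = 4 each), a difference within the spread between livers (exact permutation test, two-sided, p = 0.371). The share was 1.57 percentage points higher in low-protein livers within the linker libraries and 5.02 within the direct libraries, with an exact permutation p of 0.111 when livers were exchanged within library types, where the smallest p possible is 0.0556. With all livers the difference was 3.30 points, and it was 5.75 without low-protein 1, 5.02 without control 6, 1.87 without control 2, 1.63 without low-protein 4 and 1.61 without low-protein 5. The share averaged 8.84% in linker and 17.2% in direct libraries. Leaving out 1 liver makes the diets unequal by library type, so these shifts hold a part that comes with the type. By single miRNAs, 6 of the 9 family members were higher in low-protein livers and 3 lower (let-7b-5p, let-7e-5p and let-7i-5p), but all 9 were higher when total miRNA reads set the scale and 7 with the trimmed mean of M values. Total miRNA reads moved the median log2 difference of all miRNAs from 0.016 to 0.11. The list as a whole did not pass camera (adjusted p = 0.307).

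Of the 11 lists with at least 3 measured members, limma's camera with the preset correlation called 2, striated muscle higher and the Dlk1-Dio3 imprinted cluster lower in low-protein livers. Neither call held with an estimated correlation (adjusted p = 0.147 for striated muscle and adjusted p = 0.395 for the cluster). The striated muscle miRNAs miR-1a, miR-133a and miR-206, which are made in muscle fibres, were all higher, and 0 of the 3 passed the limma test over all miRNAs or adjusted over the list alone. With library type as a term, 0 passed over all miRNAs and 3 adjusted over the list alone. For miR-133a-3p only reads with the panel's 5′ end were counted, and the most frequent start in that arm lay 1 nt later. miR-1a-3p was at 1368 ± 1798 in low-protein and 62.9 ± 30.6 in control livers, miR-206-3p at 104 ± 159.9 in low-protein and 1.75 ± 1.41 in control livers and miR-133a-3p at 50.8 ± 74.3 in low-protein and 4.48 ± 6.90 in control livers. The excess stood mainly in 2 livers, with miR-1a-3p at 3965 in low-protein 4, 1179.8 in low-protein 8, 272 in low-protein 5 and 56.3 in low-protein 1, against 34.6 to 99.4 in controls. camera gave the list an adjusted p of 1.07e-05 with the preset correlation. With library type as a term this was 0.0107 and, as adjusted p, 0.707 with an estimated correlation. The log2 difference of miR-1a-3p was 2.25 in the linker and 4.22 in the direct libraries. Without low-protein 4 and 8 the median log2 difference of the list was 1.38, at a camera adjusted p of 0.0440, and the count of miRNAs called stayed at 0, with 0 at an unadjusted p under 0.05.

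**Figure D2:**
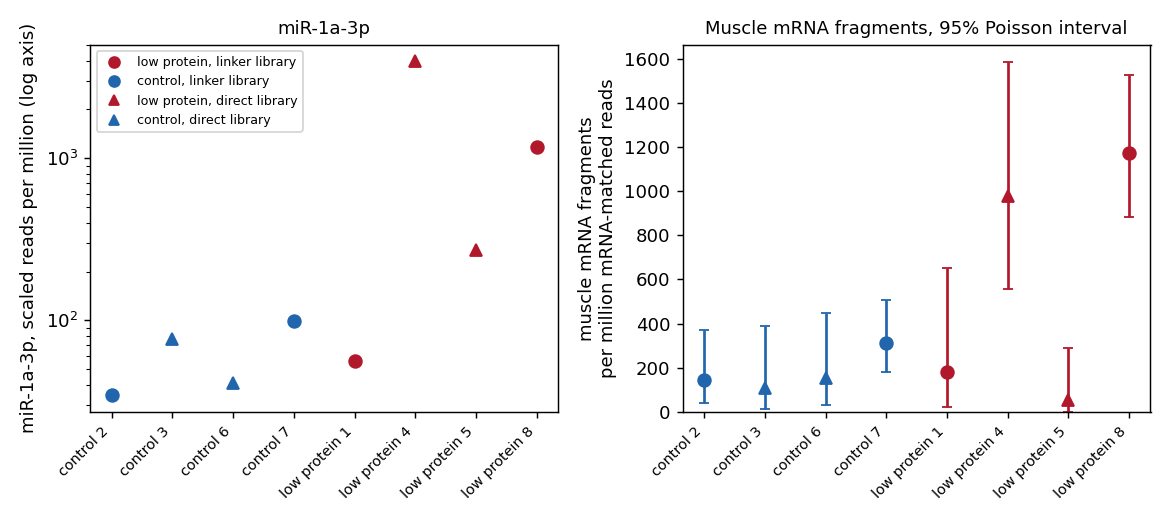
Left, scaled RPM of miR-1a-3p (log axis) in each liver; right, fragments of muscle mRNAs RPM of mRNA-matched reads with 95% Poisson intervals that cover counting error only. Low-protein 4 and 8 stand above the other 6 livers in both measures. Low-protein 4 and control 7 each held 16 muscle reads, among 16398 and 51221 mRNA-matched reads.

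The Dlk1-Dio3 cluster, a group of miRNAs made from the maternal copy of an imprinted region, had 2 of its 10 measured members higher and 8 lower in low-protein livers, and 0 passed the limma test over all miRNAs or adjusted over the list alone. Its median log2 difference was -0.30, and with total miRNA reads as the scale 4 members were higher and 6 lower. Within both library types alike, 2 members were higher and 6 lower. camera gave an adjusted p of 0.0326 with the preset correlation. The call was lost with library type as a term, where the median was -0.30 (camera adjusted p = 0.137). It was also lost without low-protein 1, where the median was -0.13 (0.458), control 3 (-0.24, 0.124), control 6 (-0.34, 0.137) or control 7 (-0.36, 0.222), each given with its camera adjusted p. Fits without 1 liver had no term for library type, and the diets were then unequal by type. The median was -0.48 without control 2, -0.47 without low-protein 8 and -0.59 without low-protein 4 and 8, with a camera adjusted p of 7.13e-04 for the last. Its members miR-541-5p, at 453 ± 160.1 in low-protein and 625 ± 100.1 in control livers, miR-382-5p, at 94.6 ± 38.5 in low-protein and 136 ± 37.5 in control livers, and miR-134-5p, at 5.47 ± 2.00 in low-protein and 9.34 ± 3.47 in control livers, were among the 5 miRNAs with the smallest p on the lower side.

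The other lists tested did not pass camera with all 8 livers: the study's list (adjusted p = 0.307), hepatocyte miRNAs (adjusted p = 0.470), miRNAs of lipid and glucose metabolism (adjusted p = 0.563), the proliferation-associated miR-17-92 cluster with its paralogs (adjusted p = 0.424), mesenchymal and stellate (adjusted p = 0.743), haematopoietic (adjusted p = 0.475), epithelial and biliary (adjusted p = 0.203) and the X-linked miR-322 and miR-450 cluster (adjusted p = 0.949). The mesenchymal list had a median log2 difference of -0.0069 and a mean of 0.056, and camera's direction was up; the X-linked cluster had a median of 0.18 and a mean of 0.025, and camera's direction was down. fry called 0 of the 11. Leaving out 1 liver brought in the let-7 family without low-protein 1 (camera adjusted p = 0.0120) or control 3 (0.0202). The study's list came in without low-protein 1 (camera adjusted p = 0.0128) or control 3 (0.0202). Its 13 measured members include the 9 of the let-7 family, so these calls are not separate. Haematopoietic miRNAs came in without low-protein 4 (camera adjusted p = 0.0194), and epithelial and biliary miRNAs without low-protein 5 (0.0396). These fits had no term for library type, and with 1 liver left out the diets were unequal by type. Without low-protein 1 or control 3, direct libraries weighed more among low-protein than among control livers. The let-7 share of miRNA reads averaged 8.84% in linker and 17.2% in direct libraries. Diet and library type therefore cannot be told apart in these calls.

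Markers of other cells of the liver, of blood and of bile ducts showed no called difference either, with 0 members past the limma test in any of these lists. Among mesenchymal miRNAs, miR-143-3p was at 7987 ± 1648 in low-protein and 11383 ± 6068 in control livers, miR-125b-5p at 3599.9 ± 531 in low-protein and 4001 ± 817 in control livers and miR-99a-5p at 1157 ± 301 in low-protein and 1230.3 ± 317 in control livers. Of the miRNAs of blood cells, the erythroid miR-451a was at 7854 ± 5823 in low-protein and 5584 ± 2364 in control livers, miR-142a-3p at 526 ± 207 in low-protein and 467 ± 254 in control livers, miR-146a-5p at 656 ± 310.5 in low-protein and 663 ± 280.4 in control livers and the erythroid miR-144-3p at 391 ± 471 in low-protein and 324 ± 298 in control livers. The endothelial miR-126a-3p was at 6455 ± 3250.2 in low-protein and 7111 ± 3095 in control livers and miR-126a-5p at 5158 ± 3120.2 in low-protein and 4713 ± 3511 in control livers, and this pair was too small a list for camera, as were the 2 neural miRNAs measured. Among epithelial miRNAs, miR-31-5p was at 441 ± 290.1 in low-protein and 448 ± 317 in control livers, miR-200b-3p at 426 ± 218 in low-protein and 393 ± 206 in control livers, miR-203-3p at 359 ± 50.1 in low-protein and 309 ± 47.6 in control livers and miR-200a-3p at 243 ± 55.0 in low-protein and 258 ± 21.9 in control livers.

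Besides the 3 muscle miRNAs, the miRNAs with the smallest p on the higher side were miR-350-3p, at 19.5 ± 5.76 in low-protein and 11.5 ± 4.61 in control livers, and miR-10b-5p, at 30.5 ± 4.52 in low-protein and 22.03 ± 3.83 in control livers. On the lower side miR-210-3p and miR-30a-5p, at 4653 ± 393 in low-protein and 6061 ± 1695 in control livers, stood beside the 3 cluster members given above. The hepatocyte-enriched miR-192-5p was at 25714 ± 5716 in low-protein and 28309 ± 13567 in control livers, and miR-148a-3p at 18902 ± 15016 in low-protein and 27565 ± 27824 in control livers. The metabolic miR-29a-3p was at 10662 ± 6277 in low-protein and 12239.9 ± 7858 in control livers. The large SD of several of these means comes with the library type, as miR-148a-3p shows, and in simulated data the fit without that term recovered 14.8% of 2-fold and 56.8% of 4-fold changes over the 159 miRNAs, against 74.5% and 94.8% with it.

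**Figure D3:**
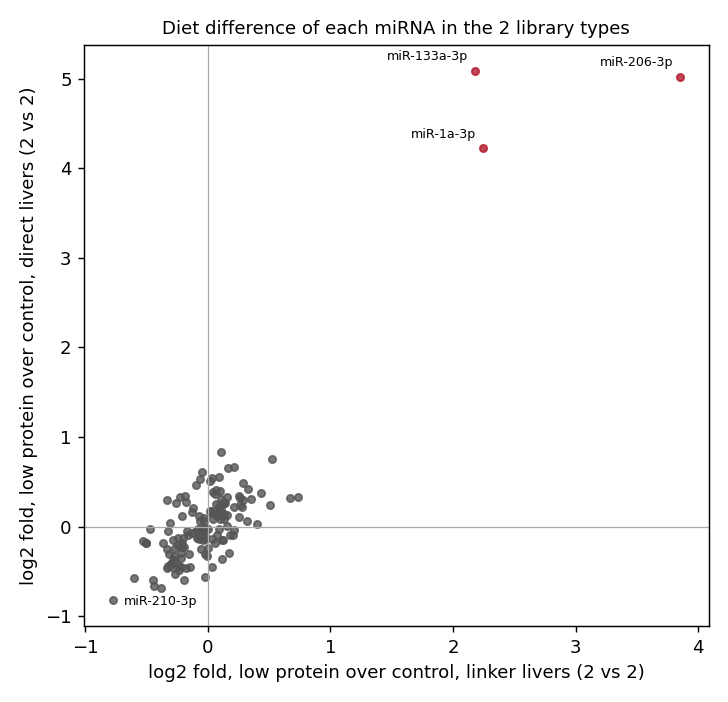
Log2 fold between low-protein and control livers of each miRNA with a mean of at least 100 reads, in the 4 linker libraries (x axis) and the 4 direct libraries (y axis), 2 livers against 2 in each. The 3 muscle miRNAs (red) lie far from the other miRNAs, and miR-210-3p is the lowest in the direct libraries.

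Of the small RNA classes in the liver, miRNAs made up 82.9% ± 1.56 in low-protein and 82.5% ± 0.407 in control livers of trimmed reads of at least 20 nt, and inserts of 20 to 24 nt 94.4% ± 0.711 in low-protein and 93.5% ± 0.976 in control livers (SD, n = 4). Fragments of mitochondrial tRNAs made up 0.293% ± 0.0993 in low-protein and 0.386% ± 0.0477 in control livers. Fragments of mRNA or long RNA made up 0.534% ± 0.348 in low-protein and 0.665% ± 0.338 in control livers, and rRNA 0.516% ± 0.213 in low-protein and 0.497% ± 0.161 in control livers. Of the 10 length and class measures, 0 passed the exact permutation test after Benjamini-Hochberg adjustment (smallest adjusted p = 0.857), and 0 had an unadjusted p under 0.05. The smallest p possible was 0.0286, so a measure could pass only if at least 6 of the 10 reached it together, and the 0 says little about a difference. In 36 nt reads an insert longer than 30 nt leaves too little adapter to be trimmed, so the longest class held 30 nt inserts only.

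Fragments from the 5′ ends of tRNAs were led by tRNA-Glu-CTC, at 2181 ± 1229 RPM of miRNA reads in low-protein and 2153 ± 368 in control livers (SD, n = 4). tRNA-Asp-GTC fragments were at 278 ± 207 and 164 ± 117, and tRNA-Val-CAC fragments at 724 ± 737 and 561 ± 428. Of the 7 tRNAs, 0 passed the exact permutation test and 0 had an unadjusted p under 0.05 (smallest p = 0.371). The smallest p possible was 0.0286, so a measure could pass only if at least 5 of the 7 reached it together, and the 0 says little about a difference.

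The 3′ ends of miR-122-5p were spread over several lengths in both groups. The 22 nt form took 28.2% ± 6.47 in low-protein and 28.8% ± 5.71 in control livers of miR-122-5p reads, the 21 nt form 23.9% ± 3.87 in low-protein and 22.8% ± 5.30 in control livers, and forms beyond 22 nt 44.4% ± 3.36 in low-protein and 45.3% ± 1.96 in control livers (SD, n = 4). The 22 nt form with an added A, which the hairpin does not encode, took 13.1% ± 2.14 in low-protein and 14.2% ± 1.71 in control livers. Of these 4 shares, 0 passed the exact permutation test between diets (smallest unadjusted p = 0.429) and 0 had an unadjusted p under 0.05. The smallest p possible was 0.0286, so a measure could pass only if at least 3 of the 4 reached it together, and the 0 says little about a difference. They differed more by library type, the 22 nt form taking 33.6% ± 1.87 in linker and 23.4% ± 1.15 in direct libraries (n = 4).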

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

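Of the groups of 4 livers examined, 2 (1.64%) held a liver far from the others. Each diet has 2 livers of each library type, so values that differ by type fall 2 against 2. A single liver can then hardly stand apart, so this share cannot be set against the 1 in 20 groups that chance gives. let-7i-5p stood at 4885 scaled RPM in low-protein 8, against 2742 to 2900.3 in the other 3 low-protein livers. miR-203-3p stood at 285 in low-protein 8, against 376 to 394 in the other 3.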

How the results depend on the processing

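The alternatives that use library type, 1 library type, hairpin arms, reads without adapter, the GC slope, a block or the omission of low-protein 4 and 8 were chosen after seeing the data. The count of miRNAs past the threshold was 0 with limma in the 36 alternatives without a block, with 0 to 21 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0686 to 1.000, the lowest without low-protein 1 and with library type as a term. The labels pair no livers, since the numbers of the titles do not recur between the diets and no shared litter or batch is given. As a hint from the data, not the design, 7 of 8 livers had their consecutive number as nearest library, by the SD of log2 differences, but the margin was small for control 2 (0.497 against 0.504) and low-protein 5, and low-protein 4 lay nearest to low-protein 5. Deviations from the means of diet and library type correlated at 0.481 in linker and 0.314 in direct couples, 1 independent value each. With these couples as a replicate block, run before the pairing was decided, the count was 4, with 17 at an unadjusted p under 0.05. These were miR-210-3p -0.80, miR-1a-3p 3.77, miR-206-3p 4.73 and miR-133a-3p 3.55. Of the other 3 couplings within library types, 1 called the same 4 and 2 called 0. Leaving out the couple low-protein 1 and control 2 gave 5, control 3 and low-protein 4 4, low-protein 5 and control 6 1, and control 7 and low-protein 8 4. Exchanging diets within couples gave 0 in the other 7 splits, where a share cannot fall under 0.125. The count of lists with the block was 1 with camera, 0 with an estimated correlation and 1 with fry, each 1 being striated muscle. Of the values for named miRNAs, lists and single tRNAs in alternatives set before the data were seen, 787 kept direction and side of the threshold, 123 turned sign, 8 were no longer past it and 6 came to pass it. In those set afterwards 726 kept both, 43 turned sign, 9 were no longer past it and 4 came to pass it. The 2 lists called became 0 with an estimated correlation, 0 with fry and 1 with library type as a term, and 0 there with an estimated correlation or fry. Without 1 liver the count of lists was 1 to 3, with 1 without control 6 or control 7. Library type was not a term in these fits, where the diets were unequal by type. The let-7 family and the study's list, which overlap, were counted separately. The count-model tools planned were not run. Values not past a test turned sign in these settings, and the cause was not tested: log2 differences or differences in share (percentage points) or in RPM were, with total miRNA reads as library size miR-192-5p 0.062, let-7b-5p 0.10, let-7e-5p 0.066, let-7i-5p 0.065, miR-99a-5p 0.0037, miR-146a-5p 0.037, the list hepatocyte 0.011, the list lipid and glucose metabolism 0.033, the list mesenchymal and stellate 0.084. With a mean of at least 100 reads miR-192-5p 0.0015, let-7b-5p 0.023. With a 5′ end free by 1 nt miR-192-5p 0.021. With sample quality weights miR-192-5p 0.14, miR-148a-3p 0.33, miR-29a-3p 0.24, let-7b-5p 0.23, let-7e-5p 0.26, miR-142a-3p -0.015, miR-144-3p -0.81, miR-126a-5p -0.17, miR-31-5p -0.42, miR-200b-3p -0.21. In linker livers miR-192-5p 0.17, let-7i-5p 0.027, miR-126a-3p 0.030, miR-31-5p -0.078. Without both livers with muscle miRNAs miR-192-5p 0.015, let-7c-5p -0.060, miR-146a-5p 0.11, miR-200b-3p -0.10, the list lipid and glucose metabolism 0.0029. Library type as a term, without both livers with muscle miRNAs miR-192-5p 0.0027, let-7c-5p -0.078, miR-146a-5p 0.14, miR-200b-3p -0.083. With the trimmed mean of M values let-7b-5p 0.027, the list mesenchymal and stellate 0.016. With the whole sequence matched let-7b-5p 0.037, let-7i-5p 0.0081, miR-199a-5p -0.0077, miR-144-3p -0.11, miR-200b-3p -0.0097. With all hairpin arms let-7b-5p 0.023. With all arms and library type let-7b-5p 0.016. Reads without a recognised adapter counted too let-7b-5p 0.013. Without the GC slope let-7b-5p 0.0023, miR-144-3p -0.13, miR-200b-3p -0.0028. In direct livers let-7e-5p 0.12, miR-144-3p -0.092. MiRNA reads without miR-122 as library size miR-144-3p -0.087, miR-31-5p -0.057, miR-200b-3p -0.00097. Over unique sequences RNA class composition: tRNA fragment -0.00300, RNA class composition: rRNA -0.0908, RNA class composition: unmatched 1.24. In reads of at least 28 nt tRNA-Gly-CCC 1.57, tRNA-His-GTG 0.143. Where library type is not a term, leaving out 1 liver makes the diets unequal by type. Differences between the types can then enter the ranges that follow. Leaving out each liver, with or without library type as a term for miRNAs, gave these ranges where a sign turned: let-7a-5p -0.039 to 0.49, miR-192-5p -0.33 to 0.23, miR-148a-3p -0.80 to 0.35, let-7c-5p -0.054 to 0.45, let-7d-5p -0.25 to 0.54, miR-29a-3p -0.57 to 0.15, let-7b-5p -0.24 to 0.27, let-7e-5p -0.32 to 0.17, let-7i-5p -0.25 to 0.054, miR-199a-3p -0.049 to 0.68, miR-99a-5p -0.27 to 0.025, miR-451a -0.11 to 0.61, miR-146a-5p -0.34 to 0.19, miR-142a-3p -0.10 to 0.50, miR-144-3p -0.83 to 0.58, miR-126a-3p -0.48 to 0.050, miR-126a-5p -0.27 to 0.69, miR-31-5p -0.36 to 0.37, miR-200b-3p -0.18 to 0.41, the list let-7 family -0.039 to 0.33, the list named by the study -0.0032 to 0.33, the list lipid and glucose metabolism -0.076 to 0.035, the list miR-17-92 and paralogs -0.017 to 0.21, the list mesenchymal and stellate -0.23 to 0.12, the list haematopoietic -0.27 to 0.51, the list X-linked miR-322 and miR-450 cluster -0.11 to 0.27, inserts of 25 to 29 nt -0.433 to 0.0553, RNA class composition: miRNA -0.399 to 0.725, RNA class composition: tRNA fragment -0.00915 to 0.0124, RNA class composition: rRNA -0.0866 to 0.0963, RNA class composition: mRNA or long RNA -0.303 to 0.0353, RNA class composition: unmatched -0.561 to 0.471, tRNA-Glu-CTC -368 to 461, tRNA-Gly-CCC -41.3 to 36.7, tRNA-Gly-GCC -16.2 to 10.3, tRNA-His-GTG -2.42 to 2.22, tRNA-Lys-CTT -102 to 197, tRNA-Val-CAC -196 to 374, miR-122 21 nt -0.403 to 2.69, miR-122 22 nt -2.92 to 1.53, miR-122 beyond 22 nt -1.77 to 0.638.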

Other observations

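Chosen only after the result was seen were the tests of miR-1a in all low-protein livers, of diet against library type, of the correlation between library types (by other splits, GC content and the muscle miRNAs) and of the splits by miRNA counts; the tests of muscle mRNA fragments, of the last base and of the splits by lists were fixed before. Counting all 386 hairpin arms took in passenger strands. With library type as a term camera placed 14 let-7 arms higher in low-protein livers (adjusted p = 0.0332, or adjusted p = 0.159 with an estimated correlation), of which 11 were higher in both library types and 0 lower in both. The 19 arms of the study's list, which holds the let-7 family and is not independent evidence, gave a camera adjusted p of 0.0332. With an estimated correlation the camera adjusted p was 0.159. The 15 epithelial and biliary arms gave 0.0468 and, as adjusted p, 0.570 with an estimated correlation. Of 43 arms of the Dlk1-Dio3 cluster, 20 were lower and 8 higher in both library types (camera adjusted p = 0.162). limma passed 0 of the 386 arms, with 2 at an unadjusted p under 0.05 without covariates, and 0 with library type as a term, with 21 at an unadjusted p under 0.05. Chosen after their values were seen, the arm Mir1247-5p was at 92.0 ± 18.1 in low-protein and 158 ± 43.3 in control livers, and Mir802-3p, the passenger of the hepatocyte miR-802, at 60.4 ± 19.03 in low-protein and 87.2 ± 29.4 in control livers. Among 135 miRNAs with a mean of at least 100 reads, without the muscle miRNAs, 11 had both low-protein livers outside both controls the same way in both library types, including miR-378a-3p, miR-22-3p and miR-152-3p (lower) and miR-92a-3p (higher). Chance gives 5.56% of miRNAs, and other splits within library types gave 0 to 22.

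The muscle miRNAs of low-protein 4 and 8 were weighed against 2 explanations. Fragments of 26 muscle mRNAs, listed before they were counted, stood at 976 RPM of mRNA-matched reads in low-protein 4 (16 reads, 95% Poisson interval 558 to 1585) and 1172 in low-protein 8 (55 reads, 883 to 1525), against at most 312 in controls, with Ttn and Myh1 the most frequent. This is consistent with muscle carried over in the liver piece, a hypothesis, and 12 hepatocyte mRNAs made up 55129 and 60168 RPM there and 45745 to 69809 in controls. The highest control, control 7, held 16 muscle reads too (95% Poisson interval 179 to 507 RPM), as many as low-protein 4. Its mRNA-matched reads numbered 51221, against 16398 in low-protein 4. The excess of low-protein 4 therefore rests on that scale, and was absent against panel miRNA reads (3344977 in control 7, 3581127 in low-protein 4). A rise in liver cells with the paternal diet stays open: 3 of the 4 low-protein livers lay above the highest control in miR-1a-3p, and a single liver below it excludes nothing. Low-protein 5, at 272 for miR-1a-3p with 51.8 RPM of muscle mRNA fragments (1 read, 95% Poisson interval 1.31 to 289), has too few reads to tell.

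The split of the libraries was weighed against paternal diet, the sequencing run and unequal ligation. Each library type held 2 livers of each diet, so the 0 miRNAs that diet called with library type as a term, against 100 between types, could not have tested diet as its source. The adapter, the library preparation and the run, with 100 tiles for linker and 330 for direct libraries, coincide and cannot be told apart. Ligation that depends on the last base of the miRNA predicted a share of variance above chance. The last base of the panel sequence explained 1.29% of the variance of the log2 fold between library types over 138 miRNAs. This was below the 95th percentile of permutations at 5.69%. The molecules ligated can end elsewhere: the 22 nt form took 33.6% of miR-122-5p reads in linker and 23.4% in direct libraries. The test therefore cannot decide on ligation by the actual last base, which stays open. Preferences that depend on several bases or on structure were not tested and stay open too.

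Diet differences correlated between linker and direct libraries, at r = 0.619 across 135 miRNAs without the muscle miRNAs and 0.881 with them; miRNAs are not independent replicates. The highest of the other splits within library types was 0.598, and 1 of the 18 splits, the real one, was as high, so the share cannot fall under 0.0556. Exchanging the diets in 1 library type only turns the sign of the correlation, so the splits come in mirrored pairs. By size without sign, the real split is tied with its mirror at -0.619. The correlation of 0.619 was computed without the muscle miRNAs, so they did not produce all of it. A split that ignores diet reached 0.598 on the same miRNAs, so whether the remainder exceeds chance cannot be told. The criterion for the muscle miRNAs was written after the result. Without each library's slope on GC content the correlation of 0.619 became 0.568, under the highest other split at 0.603. GC content may therefore contribute and stays open. The criterion for GC content and its reading were settled after both correlations had been seen, and the drop was small. A difference that goes with the paternal diet also stays open.

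Other splits of the 8 livers were put through the same fits. For miRNAs the real split called 0, which every split reaches (35 of 35, and 34 of 34 with library type as a term), so these counts say nothing about chance. The split that follows library type called 100, which points to that structure of the samples, and with library type as a term the highest other split called 11. For lists, 14 of 35 splits called at least the 2 of the real split, and the highest other called 4, so chance cannot be excluded for the number of lists.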
